A study of Mus musculus with 4 samples.

How the data were processed

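The data are 4 expression arrays of RNA from brown-like adipocytes made in culture, 2 from wild-type and 2 from Lgr4 homozygous mutant mice. Per the labels' protocols, SVF cells from epididymal white fat were grown in DMEM with 10% fetal bovine serum and 10 ng/ml basic fibroblast growth factor until confluent. They were then induced for 48 h with insulin (5 µg/ml), isobutylmethylxanthine (0.5 mM, a phosphodiesterase inhibitor that raises cAMP), dexamethasone (1 µM), the thyroid hormone T3 (50 nM) and troglitazone (5 µM, an agonist of PPAR gamma). A further 6 days followed in growth medium with insulin, T3 and troglitazone. Since troglitazone and T3 were present in both genotypes, the arrays compare genotypes under strong induction. Biotinylated RNA was made from 500 ng of total RNA with an Affymetrix 3' kit, whose probes lie near the 3' end of transcripts.

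The deposited values are log2 signals per probe set, and per the submitters' processing notes they were made with Partek 6.6 and RMA. RMA subtracts background, makes the distributions of the arrays equal and summarises the probes of a probe set. It compresses differences near background and near the top of the range, and making the distributions equal removes differences in total RNA between cultures. After summarising, the deposited distributions were close but not equal. Upper quartiles were 8.56 and 8.52 on the wild-type arrays and 8.48 and 8.47 on the mutant arrays. Which variant of RMA was run was not given in the sources used here, and the log2 scale was read from the values, which ran from 2.86 to 15.2. The table held 45101 probe sets, of which 64 were controls and were left out. Gene names came from a table of the platform's annotation: 34945 probe sets named 1 gene, 932 named several and 9160 other than controls named none. Only probe sets naming 1 gene were used, giving 18194 genes, and genes without such a probe set were not analysed here. Of these probe sets, 204 had a gene that was not matched in the RefSeq gene table (assembly GRCm38.p6), which was used only for current names and for the order of genes.

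For each gene the probe set with the highest mean over the 4 arrays was used. It was tested if this mean exceeded the 40th percentile of all probe sets other than controls, a log2 signal of 6.13, which left 13173 genes. Named genes below this filter have values from the same fit run on all 18194 genes. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All p-values of single genes are 2-sided, and each ± is an SD over the 2 arrays of a genotype. With 2 against 2 arrays there are 2 residual degrees of freedom, to which limma added 6.21 prior degrees of freedom from the spread of all genes (prior SD 0.104). The number of arrays limits the precision. The labels call the arrays biological replicates without saying whether each came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Median absolute difference between replicates was 0.14 in the wild-type pair and 0.0726 in the mutant pair, and no array was left out.

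The fit was tested on simulated data for this comparison with 13173 genes, of which a seeded set was changed by known amounts. It recovered 25 of 67 genes changed by 0.5 on the log2 scale (37.3%), 66 of 67 changed by 1 (98.5%) and 66 of 66 changed by 2, and 8 unchanged genes were called, or 4.85% of the calls. With no change simulated, limma called 0 genes, and 663 (5.03%) had an unadjusted p under 0.05. In simulated lists of 20 genes, camera gave a p under 0.05 for 7 of 100 lists without a shift and for 20 of 20 lists shifted by 0.3. Simulated genes were independent, the lists were random and both genotypes had the same spread. The simulation could therefore not check the preset correlation, since correlations estimated in the real lists reached 0.261. It also changed far fewer genes than the 3924 called in the data, and the real pairs differed in spread.

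Before the data were examined, 25 gene lists with 712 members (674 on the array) were written from textbook knowledge. They were the brown and thermogenic program, beige markers, white markers, general adipocyte genes, fatty acid and triglyceride synthesis, fatty acid oxidation, respiratory chain and ATP synthase, citric acid cycle and mitochondrial biogenesis, Wnt targets, Wnt components, cAMP signalling, retinoblastoma and E2F genes, proliferation, progenitors, extracellular matrix, smooth muscle and mural cells, macrophages, lymphocytes, endothelium, mesothelium and epithelium, inflammation, interferon-stimulated genes, stress, glycolysis and hypoxia, and genes around Lgr4. Each list was tested against the other genes with camera, with a preset correlation between genes of 0.01, and adjusted over the 25 lists. Of these, 16 passed, 10 upward and 6 downward. No list passed when the correlation was estimated from the 4 arrays, 4 lists having an unadjusted p under 0.05 and the lowest adjusted p being 0.233. Lists with an estimated correlation below the preset 0.01 failed too. For the white list (-0.0437) the unadjusted camera p went from 2.4e-05 to 0.0462, and for glycolysis and hypoxia (-0.0129) from 4.42e-04 to 0.0618. With 2 residual degrees of freedom, these failures alone do not show that correlation between genes accounts for the shifts. Under fry, which tests whether the genes of a list move one way and makes no comparison with other genes, 18 passed. For each list the single-gene p-values were also adjusted over the list alone.

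The genes named were set by a rule fixed before the data were examined. They were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out clone and predicted names, 16 genes of prior interest (Lgr4, Ucp1, Cidea, Prdm16, Ppargc1a, Dio2, Elovl3, Cox7a1, Cox8b, Pparg, Cebpa, Fabp4, Adipoq, Lep, Rb1 and Axin2), and up to 4 genes with the smallest p from each list. Genes outside the rule are marked as named after their values were seen. No named gene had another probe set above the filter that was called in the opposite direction.

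Alternatives fixed in advance were no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set tested, an intensity trend in the variance with and without robust estimation, a second quantile normalization, centring each array on its median, the replicate number as a block, leaving out each array in turn, a 1.5-fold minimum, an adjusted p of 0.1, and for lists an estimated correlation and fry. Tests of gene lists against each other and of gene order were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. The labels gave no batch or scan date.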

Results

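Gene expression was measured in brown-like adipocytes that had been differentiated in culture from the stromal vascular fraction (SVF) of mouse epididymal white fat. The SVF is the mixture of preadipocytes, immune, vascular and other cells that remains when mature fat cells are removed from adipose tissue. Donors were 4-month-old male mice, either wild-type or homozygous for a mutant allele of Lgr4, a receptor for R-spondins that raises the response of cells to Wnt ligands. Each genotype was represented by 2 arrays, described as biological replicates, so 4 arrays entered the comparison. The question posed by the design was whether SVF cells without normal Lgr4 turn more readily into brown-like adipocytes. The deposited values were log2 signals from a 3' expression array. Median signal was 6.66 on both wild-type arrays and 6.69 on both mutant arrays. Over all probe sets the correlation between arrays was 0.9953 within the wild-type pair, 0.9977 within the mutant pair and 0.982 to 0.9867 across genotypes, probe sets not being independent replicates.

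Lgr4 signal was lower in the library pair labelled mutant. The probe set used for Lgr4 read 8.65 and 8.20 on the wild-type arrays and 6.18 and 6.09 on the mutant arrays, a log2 difference of -2.29 (SE 0.14, adjusted p = 1.45e-05), or 4.90-fold lower, with the mutant mean at the signal filter of 6.13. A second Lgr4 probe set, which lay below the signal filter, read 5.28 and 5.23 in wild-type and 5.37 and 5.31 in mutant cultures. The nature of the mutation and its position relative to these probe sets were not given in the sources used here, so the first probe set checks the labels only as far as the transcript it detects.

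The genotypes differed across much of the transcriptome, and the 12 largest rises in the mutant were larger than the largest fall. Of 13173 genes tested, 3924 (29.8%) passed an adjusted p of 0.05 in limma: 1456 were higher in the mutant and 2468 lower. Large changes ran the other way in number, with 379 genes at least 2-fold higher and 159 at least 2-fold lower, 110 against 13 at 4-fold, and 41 against 1 at 8-fold. Thrsp, which is induced with fatty acid synthesis, rose from 7.85 ± 0.0035 to 12.82 ± 0.13 (SD, n = 2 per genotype), a 31.3-fold difference (log2 4.97, and 3.07 when all its probe sets were averaged). The other 11 of the 12 largest rises lay between 15.3-fold and 26.9-fold. They were Aldh1a7 (an aldehyde dehydrogenase, log2 difference 4.75), Retn (the adipokine resistin, 4.49), Acaa1b (a peroxisomal thiolase, 4.33), Elovl3 (a fatty acid elongase of brown fat, 4.16), the carboxylesterases Ces1f (4.12) and Ces1d (4.05), Cdo1 (cysteine dioxygenase, 4.09), Ffar4 (a receptor for long-chain fatty acids, 4.01), Adig (adipogenin, 3.97), Cidec (a lipid droplet protein, 3.96) and Cox8b (a cytochrome c oxidase subunit of brown fat and muscle, 3.94). Wild-type means of Ces1f (4.53), Ffar4 (5.14), Ces1d (5.52), Acaa1b (6.05) and Elovl3 (6.07) lay below the signal filter of 6.13, so their folds are against a signal near background and their order is not exact. Standard errors of these 12 differences ran from 0.091 for Cidec to 0.20 for Elovl3.

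The 12 largest falls included Lgr4 itself. Col8a1, a short-chain collagen, fell from 10.88 ± 0.30 to 7.78 ± 0.33, or 8.62-fold, and Ccn3, a matricellular protein, fell from 11.92 ± 0.26 to 9.06 ± 0.19, or 7.24-fold. After Lgr4 followed Hs6st2 (a heparan sulfate sulfotransferase, -2.23), Ifi202b (an interferon-inducible gene, -2.18), Fbn2 (fibrillin, -2.17), Thy1 (a mesenchymal surface antigen, -2.17), Pamr1 (-2.14), Ahr (the aryl hydrocarbon receptor, -2.10), Rgs5 (a pericyte marker, -2.09), Cemip (a hyaluronan-binding protein, -2.04, and -1.04 when all its probe sets were averaged) and Aspn (asporin, a matrix proteoglycan, -2.03). Mutant means of Ifi202b (5.32) and Rgs5 (5.66) lay below the signal filter. In 9061 of the tested genes (68.8%) the pairs of values did not overlap, against 33.3% by chance for 2 against 2, and no called gene overlapped. Higher genes made up 37.1% of the calls, and 48.5% when each array was centred on its median. Leaving out wild-type replicate 2 gave 6317 calls, leaving out mutant replicate 1 gave 1879 and leaving out mutant replicate 2 gave 2224.

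**Figure D1:**
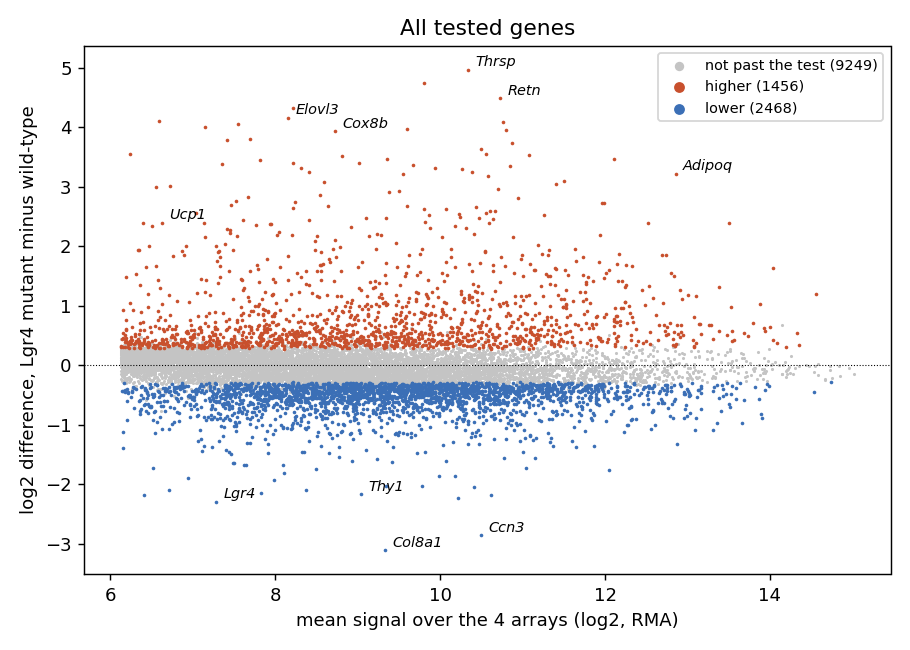
Log2 difference (mutant minus wild-type, vertical axis) against mean log2 signal over the 4 arrays (horizontal axis) for the 13173 tested genes, 1 point per gene, with 1456 genes higher (red), 2468 lower (blue) and 9249 not past the test (grey). The points above 3 are red and numerous, while Col8a1 is the single gene below -3.

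Brown-fat genes rose in the mutant cultures, although not all of the classical markers did. Ucp1, the uncoupling protein of thermogenic fat, rose from 5.43 ± 0.62 to 7.83 ± 0.48 (SD, n = 2), a 5.28-fold difference (log2 2.40, SE 0.29, adjusted p = 5.68e-04). Both wild-type values (4.99 and 5.86) lay below the signal filter, so this fold is against a signal near background. Elovl3 was 17.9-fold, Cox8b 15.3-fold and Cox7a1, another cytochrome c oxidase subunit, 2.70-fold higher (1.44, SE 0.12, adjusted p = 9.50e-05). Ppargc1a, a coactivator of mitochondrial biogenesis, lay below the signal filter in mean signal. In the fit without the filter it was 3.75-fold higher (1.91, SE 0.10, adjusted p = 4.81e-06). All 5 of its probe sets lay below the filter and rose by 1.37 to 2.53, so the size of this fold is not exact. Differences for Prdm16 (0.19, SE 0.11, adjusted p = 0.230), a transcriptional regulator of brown fat, and Dio2 (0.17, SE 0.097, adjusted p = 0.214), which makes active thyroid hormone, did not pass, nor did that of Cidea (-0.13, SE 0.10, adjusted p = 0.411), which lay below the filter. Prdm16 passed only when wild-type replicate 2 was left out (0.31, adjusted p = 0.0171).

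Of the brown and thermogenic list, 16 of 25 genes on the array passed the filter, and 10 rose, 1 fell and 5 did not pass; adjusted over the list alone the counts were 10 and 1. Its mean log2 difference was 1.18 (2.26-fold), with the list mean at 6.92 ± 0.077 in wild-type and 8.10 ± 0.096 in mutant cultures (camera adjusted p = 1.24e-07). It did not pass with an estimated correlation (adjusted p = 0.233 with an estimated correlation). Further risers were Plin5 (2.29), which coats lipid droplets near mitochondria, and Ppargc1b (1.79). The gene that fell was Acot11, an acyl-CoA thioesterase (-0.57), a call that ended when all probe sets of the gene were averaged (-0.27, adjusted p = 0.0675). Pank1 (0.22), S100b (0.079) and Bmp8b (-0.064) did not pass, with S100b (6.15) and Bmp8b (6.49) near the filter in wild-type mean signal. These last 4 genes were chosen after their values were seen. Beside this list, the general adipocyte list rose in the same cultures by a mean of 1.78 and the macrophage list fell, with a mean difference of -0.291.

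**Figure D2:**
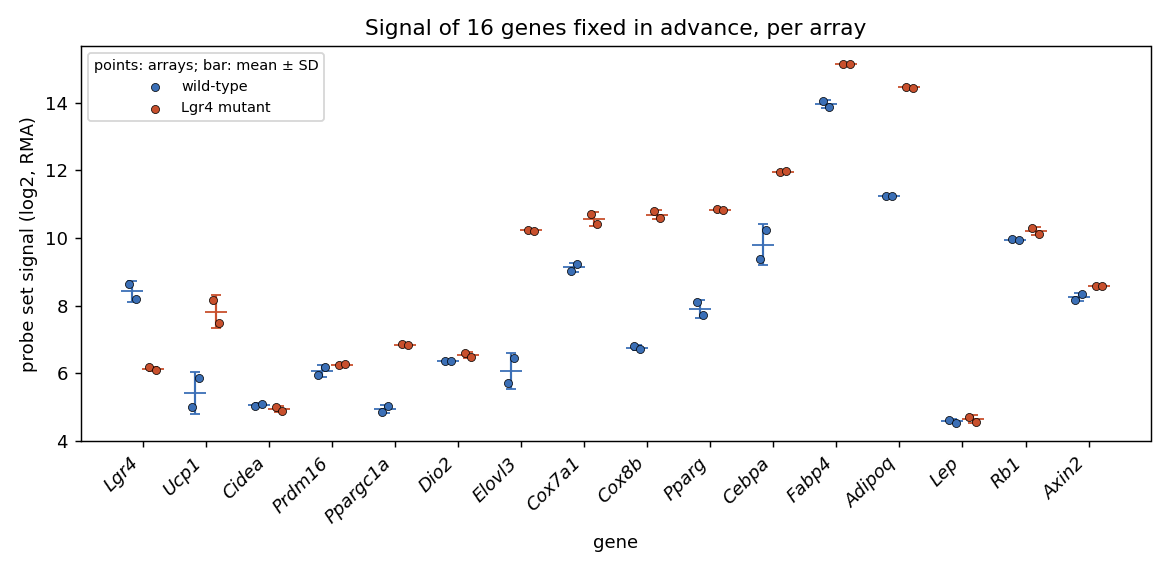
Log2 signal (vertical axis) of 16 genes fixed in advance (horizontal axis), 1 point per array, with the bar giving mean ± SD of the 2 wild-type (blue) and 2 mutant (red) arrays. Lgr4 is lower in the mutant, Ucp1, Elovl3, Cox8b, Pparg and Adipoq are higher, and Cidea, Prdm16, Dio2 and Lep differ by 0.19 or less.

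Beige-selective markers went both ways, and white adipocyte markers rose. In the beige list of 11 tested genes, 3 rose, 4 fell and 4 did not pass (4 and 5 when adjusted over the list alone), with a mean difference of 0.183 (camera adjusted p = 0.665; adjusted p = 0.729 with an estimated correlation), which passed with fry alone (adjusted p = 0.00231). Slc36a2, an amino acid transporter, rose by 3.22, whereas Sp100 (-0.68) and the progenitor receptor Pdgfra (-0.56) fell. In the white list of 14 tested genes, 8 rose, 1 fell and 5 did not pass (8 and 2 when adjusted over the list alone), with a mean difference of 1.06 (camera adjusted p = 7.49e-05; adjusted p = 0.233 with an estimated correlation). Besides Retn, the risers included Agt (angiotensinogen, 2.93), Wfdc21 (2.75) and Zfp423 (1.67), a transcription factor of white adipocyte identity whose wild-type mean (5.72) lay below the signal filter. The gene that fell was Igfbp3 (-0.88), named after its value was seen. Leptin (Lep) signal was 4.58 ± 0.068 in wild-type and 4.64 ± 0.11 in mutant cultures, below the filter in both, and its difference of 0.06 did not pass (adjusted p = 0.744).

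General adipocyte genes rose almost throughout. Pparg, the master regulator of adipogenesis, rose from 7.91 ± 0.27 to 10.84 ± 0.026 (2.92, SE 0.13, adjusted p = 2.19e-06), and its partner Cebpa from 9.81 ± 0.62 to 11.97 ± 0.028 (2.16, SE 0.23, adjusted p = 3.40e-04). The adipokine Adipoq was 9.30-fold higher (11.25 ± 0.013 against 14.47 ± 0.025). Fabp4, the fatty acid binding protein of adipocytes, was 2.29-fold higher by its brightest probe set, which read 15.15 in the mutant and so lay at the top of the signal range of these arrays. The other 3 Fabp4 probe sets were higher by 1.32 to 3.72. Of 32 tested genes in the list, 27 rose, 2 fell and 3 did not pass (29 and 2 when adjusted over the list alone), with a mean difference of 1.78 (camera adjusted p = 2.55e-23; adjusted p = 0.233 with an estimated correlation). Among the risers were Gpd1, which supplies glycerol phosphate (3.74), and the retinol carrier Rbp4 (3.54). The genes that fell were Cebpb (-0.45) and Cebpd (-0.63), both early adipogenic transcription factors, named after their values were seen. The Cebpb call ended without mutant replicate 1 (adjusted p = 0.0634) and without mutant replicate 2 (adjusted p = 0.109).

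Fatty acid and triglyceride synthesis genes showed the highest mean rise of the 25 lists. Of 23 tested genes 19 rose, none fell and 4 did not pass (20 rose when adjusted over the list alone), and the mean difference was 1.94, or 3.84-fold (camera adjusted p = 1.15e-20; adjusted p = 0.233 with an estimated correlation). Pyruvate carboxylase (Pcx) rose by 3.63, the acyltransferase Agpat2 by 3.47 and the acetyl-CoA synthetase Acss2 by 3.33.

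Genes of fat burning and of the mitochondrion rose together with those of fat synthesis, in cultures where the general adipocyte list rose by a mean of 1.78 and the macrophage (-0.291) and matrix (-0.38) lists fell. In the fatty acid oxidation list, 27 of 31 tested genes rose, none fell and 4 did not pass (28 rose and 2 fell when adjusted over the list alone). The mean difference was 1.19 (camera adjusted p = 8.59e-21; adjusted p = 0.233 with an estimated correlation). Examples were Pex11a, a peroxisomal division protein (1.85), the carnitine palmitoyltransferase Cpt2 (1.82) and the acyl-CoA dehydrogenases Acadl (1.74) and Acadvl (1.63). Nuclear-encoded subunits of the respiratory chain and ATP synthase rose less but broadly. Of 72 tested, 62 rose, none fell and 10 did not pass (67 rose when adjusted over the list alone), with a mean difference of 0.596, or 1.51-fold (camera adjusted p = 5.46e-26; adjusted p = 0.233 with an estimated correlation). Cytochrome c (Cycs) was 2.82-fold higher, and cytochrome c1 (Cyc1) rose by 1.24 and Uqcrfs1 by 1.12. Ndufab1 rose by 1.07, and by 0.60 when all its probe sets were averaged.

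Citric acid cycle and mitochondrial biogenesis genes followed, with 17 of 25 higher, none lower and 8 not past the test (18 and 1 when adjusted over the list alone). Their mean difference was 0.684 (camera adjusted p = 2.46e-10; adjusted p = 0.233 with an estimated correlation). Isocitrate dehydrogenase Idh3a rose by 2.19, and the pyruvate dehydrogenase complex genes Dlat, Pdhb and Pdhx by 1.58, 1.48 and 1.42. In the glycolysis and hypoxia list of 20 genes, 9 rose, 2 fell and 9 did not pass (9 and 2 when adjusted over the list alone), with a mean difference of 0.347 (camera adjusted p = 0.001; adjusted p = 0.233 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, rose by 1.71 and the glycolytic enzyme Aldoa by 0.57. Pfkfb3, which sets the level of a glycolytic activator, rose by 0.99, and by 0.66 when all its probe sets were averaged.

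Wnt/beta-catenin target genes were lower on balance, with exceptions, in cultures where the general adipocyte list rose (mean difference 1.78) and the matrix (-0.38) and macrophage (-0.291) lists fell. Of 21 tested, 2 rose, 9 fell and 10 did not pass, and the counts of risers and fallers were the same when adjusted over the list alone. The mean difference was -0.371 (camera adjusted p = 0.015; adjusted p = 0.283 with an estimated correlation). Nkd2, a feedback inhibitor of Wnt signalling, fell by 1.67 (-0.83 when all its probe sets were averaged), Nrcam by 1.81 and Ccn5 by 1.86. The Wnt inhibitor Apcdd1 rose by 1.58, and Axin2, a commonly used Wnt target, was slightly higher, from 8.25 ± 0.12 to 8.57 ± 0.0080 (0.32, SE 0.099, adjusted p = 0.0410). The list call ended without the signal filter, where the mean difference was -0.223 (adjusted p = 0.0555), and without wild-type replicate 2 (adjusted p = 0.0541). The Axin2 call ended without wild-type replicate 1 (adjusted p = 0.056), without mutant replicate 1 (0.242), without mutant replicate 2 (0.253), without the filter (0.0551) and with every probe set tested (0.0575).

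Among 41 Wnt components (Wnt and R-spondin ligands, receptors, secreted antagonists and intracellular genes of the pathway), 2 rose, 9 fell and 30 did not pass. The counts were 2 and 9 when adjusted over the list alone. As a list they did not pass, with a mean difference of -0.162 (camera adjusted p = 0.645; adjusted p = 0.78 with an estimated correlation). Besides Lgr4 itself, the Wnt receptors Fzd5 (-1.45), Ror2 (-1.27, and -0.76 when all its probe sets were averaged) and Fzd1 (-1.08) fell. The risers, named after their values were seen, were Rspo1, a ligand of Lgr4 (1.11), and the secreted antagonist Sfrp2 (0.38). The Sfrp2 call ended without mutant replicate 1 (adjusted p = 0.19) and without mutant replicate 2 (adjusted p = 0.111).

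Genes of cAMP signalling, which drives thermogenic gene expression in fat, did not move as a list. Of 28 tested, 5 rose, 6 fell and 17 did not pass (5 and 8 when adjusted over the list alone). The mean difference was 0.127 and the median -0.00113, so these differ in sign (camera adjusted p = 0.563; adjusted p = 0.6 with an estimated correlation). The protein kinase A regulatory subunit Prkar2b (2.35), the phosphodiesterase Pde3b (1.95) and the adenylyl cyclase Adcy6 (0.87) rose, and Gadd45b fell by 0.71. The retinoblastoma gene Rb1 read 9.95 ± 0.020 in wild-type and 10.21 ± 0.12 in mutant cultures, a difference of 0.26 that did not pass (SE 0.099, adjusted p = 0.082). It passed after a second quantile normalization (0.34, adjusted p = 0.035) and after centring on the median (0.31, adjusted p = 0.0464). In the retinoblastoma and E2F list of 22 genes, 2 rose, 9 fell and 11 did not pass (3 and 9 when adjusted over the list alone), with a mean difference of -0.163 (camera adjusted p = 0.372; adjusted p = 0.487 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn2b fell by 1.32, while Cdkn2c (0.73) and the cyclin Ccnd2 (0.62) rose.

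Proliferation genes fell in the mutant cultures. Of 36 tested, none rose, 23 fell and 13 did not pass (32 fell when adjusted over the list alone). The list mean was 9.37 ± 0.11 in wild-type and 8.93 ± 0.0066 in mutant cultures, a difference of -0.442 (camera adjusted p = 3.05e-08; adjusted p = 0.352 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 fell by 1.04, and the replication helicase subunits Mcm6, Mcm5 and Mcm3 by 0.74, 0.72 and 0.62. In the same cultures the general adipocyte list was higher by 1.78 and the macrophage list lower, with a mean difference of -0.291.

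Most called genes of the progenitor, matrix and contractile lists were lower in the mutant, beside the fall of the macrophage list. Of 18 adipose progenitor markers, 1 rose, 8 fell and 9 did not pass (3 and 10 when adjusted over the list alone). Their mean difference of -0.299 did not pass (camera adjusted p = 0.0509; adjusted p = 0.361 with an estimated correlation), though it did under 8 of the 14 alternatives, for example without the filter (-0.31, adjusted p = 0.00899). Thy1, Mfap5 (-1.32) and Anxa3 (-0.91) fell, and Sema3c rose by 1.69. Of 36 extracellular matrix and fibroblast genes, 6 rose, 21 fell and 9 did not pass (7 and 24 when adjusted over the list alone), with a mean difference of -0.38 (camera adjusted p = 8.68e-04; adjusted p = 0.414 with an estimated correlation). Thbs2 (-1.75), Timp3, an inhibitor of matrix proteases (-1.73), Col12a1 (-1.36) and Tnc (-1.18) fell. Collagen VI went the other way, with Col6a2 higher by 1.13, Col6a1 by 1.05 and Col6a3 by 0.83, named after their values were seen.

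Of 19 smooth muscle, mural and myofibroblast markers, 3 rose, 10 fell and 6 did not pass (4 and 12 when adjusted over the list alone). The mean difference was -0.364 (camera adjusted p = 0.0346; adjusted p = 0.352 with an estimated correlation). Rgs5, Synpo2 (-1.30) and the tropomyosin Tpm2 (-0.88) fell. The pericyte-associated genes Mcam (0.92), Abcc9 (0.62) and Cspg4 (0.39) rose, the last 2 named after their values were seen. The list call ended with the filter at the 60th percentile (adjusted p = 0.111) and without wild-type replicate 2 (adjusted p = 0.0799). The Cspg4 call ended without mutant replicate 1 (adjusted p = 0.21) and without mutant replicate 2 (adjusted p = 0.0831).

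Markers of other SVF cell types did not all move together. Macrophage and other myeloid markers had a list mean of 12.2 ± 0.10 in wild-type and 11.91 ± 0.021 in mutant cultures. Of 27 tested, none rose, 12 fell and 15 did not pass (13 fell when adjusted over the list alone), and the mean difference was -0.291 (camera adjusted p = 8.68e-04; adjusted p = 0.397 with an estimated correlation). Msr1, a scavenger receptor, fell by 0.90, Itgam by 0.79, Fcgr1 by 0.68 and Ptprc by 0.58. The endothelial list mean was 7.33 ± 0.025 in wild-type and 7.51 ± 0.096 in mutant cultures. Levels of different lists come from different probe sets, so they do not rank the cell types by abundance. Of 19 tested, 3 rose, 1 fell and 15 did not pass (1 rose and none fell when adjusted over the list alone), with a mean difference of 0.181 (camera adjusted p = 0.0116; adjusted p = 0.469 with an estimated correlation). Ramp2 rose by 0.61, Cdh5 by 0.42 and Sox18 by 0.37, whereas Vwf fell by 0.40. The Cdh5 call ended without the filter (limma adjusted p = 0.0513) and with every probe set tested (0.0618). It also ended without wild-type replicate 1 and without mutant replicate 1. Calls of Sox18 and Vwf ended without wild-type replicate 1 and without each mutant replicate. Without mutant replicate 1 the differences of Cdh5 and Sox18 were 0.24 and 0.29, and without mutant replicate 2 that of Vwf was -0.32. The endothelial call ended without mutant replicate 1 (mean difference 0.127, adjusted p = 0.117), with the replicate block (adjusted p = 0.138) and with fry, a rotation test (adjusted p = 0.144).

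Of 12 lymphocyte markers on the array 6 passed the filter. Ighm rose by 0.69 and the other 5 did not pass (2 rose when adjusted over the list alone), with a mean difference of 0.271 (camera adjusted p = 0.0321; adjusted p = 0.414 with an estimated correlation). That call ended without wild-type replicate 1 (adjusted p = 0.0696), mutant replicate 1 (0.0837) or mutant replicate 2 (0.0871), without the filter, where the mean difference was 0.162 (0.0719), after a second quantile normalization (0.0546), with the replicate block (0.194) and with fry (0.0507). Of 18 mesothelial and epithelial markers on the array 8 passed the filter, of which Slc39a8 fell by 0.67 and 7 did not pass (1 fell when adjusted over the list alone). Their mean difference was 0.0203 (camera adjusted p = 0.593; adjusted p = 0.654 with an estimated correlation).

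Interferon-stimulated genes fell, beside the fall of the macrophage list. Of 24 tested, none rose, 10 fell and 14 did not pass (2 rose and 12 fell when adjusted over the list alone), with a mean difference of -0.382 (camera adjusted p = 0.00126; adjusted p = 0.397 with an estimated correlation). Ifit1 fell by 1.64, Ifit2 by 1.04, Usp18 by 0.84 and Ifit3 by 0.80. Cytokines and other inflammatory genes went both ways, with 5 of 23 higher, 6 lower and 12 not past the test (5 and 8 when adjusted over the list alone). Their mean difference was -0.115, their median 0.029 and the direction of the list test upward, so the mean differs in sign from the other two (camera adjusted p = 0.9; adjusted p = 0.916 with an estimated correlation). Il6 fell by 1.89, Ccl7 by 1.58 and Ccl2, named after its value was seen, by 1.12; the mutant mean of Il6 (5.99) lay below the signal filter, so the size of its fall is not exact. Lcn2 (1.43) and haptoglobin (Hp, 1.18), both also made by adipocytes, rose. In the stress list of 27 genes, 2 rose, 6 fell and 19 did not pass (2 and 7 when adjusted over the list alone), with a mean difference of -0.16 (camera adjusted p = 0.18; adjusted p = 0.414 with an estimated correlation). The heat shock genes Hspa1b and Hspa1a fell by 1.24 and 0.75, and the endoplasmic reticulum gene Sdf2l1 by 0.66.

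**Figure D3:**
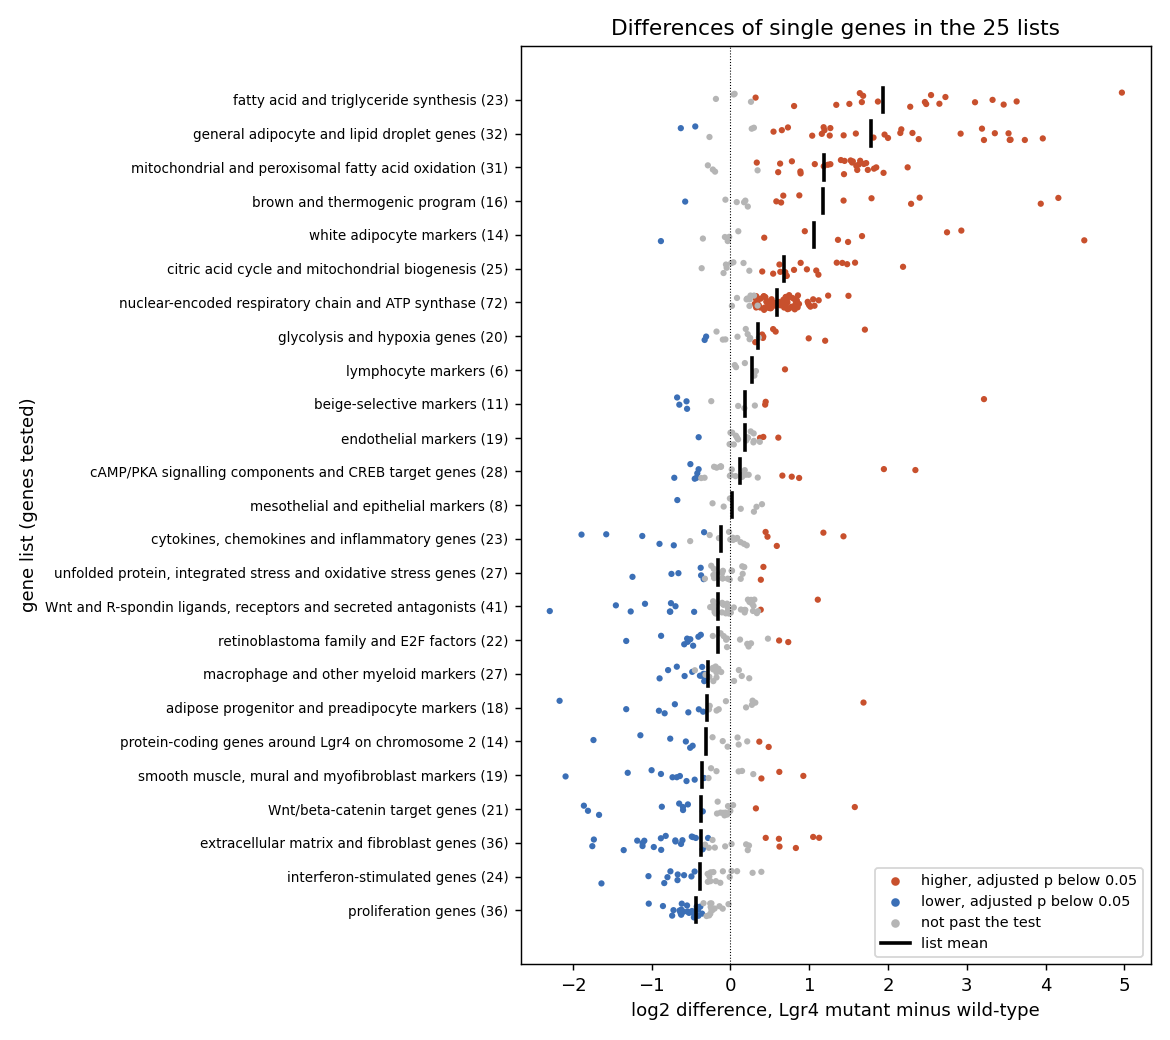
Log2 difference (mutant minus wild-type, horizontal axis) of each tested gene in the 25 lists (vertical axis, number tested in parentheses), coloured red for higher, blue for lower and grey for not past the test, with a black bar at the list mean. List means run from 1.94 for fatty acid and triglyceride synthesis to -0.442 for proliferation genes.

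Genes around Lgr4 on chromosome 2 included several that fell. Of 14 tested, 2 rose, 6 fell and 6 did not pass (2 and 6 when adjusted over the list alone), and the list did not pass, with a mean difference of -0.308 (camera adjusted p = 0.228; adjusted p = 0.533 with an estimated correlation). Fibin fell by 1.74, Bdnf (brain-derived neurotrophic factor) by 1.14, Rcn1 by 0.76 and Ccdc34 by 0.57. The mutant mean of Bdnf (5.96) lay below the signal filter, so the size of its fall is not exact. The direct neighbour Lin7c, named after its value was seen, fell by 0.51 by its brightest probe set, a call that ended without mutant replicate 1. Its 2 other probe sets above the filter were lower by 0.19 and 0.41. Neither passed in the limma fit of all probe sets naming 1 gene (adjusted p = 0.255 and 0.131).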

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

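All alternatives were planned, and no named gene or list that was called changed direction under any of them; of all 3924 calls, at most 7 changed sign under an alternative that tests 1 value per gene. The number of genes called was within 1.5 times 3924 under every change of filter, probe set rule, variance prior or scaling (3543 to 4101) and at an adjusted p of 0.1 (5146). A 1.5-fold minimum left 1501 genes, 715 higher and 786 lower. Leaving out single arrays gave 1879 to 6317 genes in all, 798 to 2620 higher and 1081 to 3697 lower. In these fits the lone array of a genotype is assumed to vary like the other pair. Lgr4 stayed lower throughout (-2.51 to -2.07 without single arrays). The thermogenic shift ran from 0.92 without the filter to 1.54 at the 60th percentile and from 1.04 to 1.27 without single arrays, and its call held in each. With an estimated correlation it stayed 1.18 but did not pass (adjusted p = 0.233), and 0 of the 25 lists passed, 4 having an unadjusted p under 0.05, against 14 to 18 under the other alternatives. This test estimates the correlation from 2 residual degrees of freedom, and it also failed lists whose estimated correlation lay below the preset 0.01. Replicate numbers are shared between genotypes, but only a number is shared: the differences of replicate 2 minus replicate 1 correlated at 0.159 between genotypes across genes. With the replicate block 4879 genes were called, including all 3924, with 36.9% higher, and 15 lists passed. Median log2 difference of all genes moved from -0.0348 to 0.0188 under the scaling alternatives. Of 144 named genes, called or not, none lost a call with centring or a second quantile normalization, while 4 gained one with centring (Rb1, Cd3d, Nkain4 and Krt8) and 2 with the normalization (Rb1 and Nkain4). Averaging all probe sets of a gene kept the sign of named calls but changed some sizes by more than 1.5 times, for example Thrsp from 4.97 to 3.07, Gpd1 from 3.74 to 2.46, Idh3a from 2.19 to 1.34, Cemip from -2.04 to -1.04, Nkd2 from -1.67 to -0.83 and Fabp4 from 1.19 to 2.34. Without the filter the Wnt target shift fell from -0.371 to -0.223 and the lymphocyte shift from 0.271 to 0.162. With fry the endothelial (adjusted p = 0.144) and lymphocyte (0.0507) calls ended, and the beige (0.00231), retinoblastoma and E2F (0.0149), stress (0.036) and progenitor (0.0188) lists passed. Except where an alternative's construction shows it (fewer arrays, other genes tested), the cause was not tested. Probe sets below the filter, such as those of Cidea and Lep, or close to it, such as those of Prdm16 and Dio2, limit what a missing difference can show.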

Other observations

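Genes grouped by the shared stem of their symbols gave further groups that moved together. Of 147 such families with at least 10 tested genes, 16 passed camera with the preset correlation, and none with an estimated correlation (1 at an unadjusted p under 0.05, and adjusted p = 0.808 for each named here). The grouping was chosen after the results of the gene lists were seen. Genes of the mitochondrial ribosome rose: 28 of 47 Mrpl genes of the large subunit (mean log2 difference 0.335, adjusted p = 6.63e-09) and 20 of 29 Mrps genes of the small subunit (0.45, adjusted p = 6.63e-09), with none lower. The same held for 11 of 14 Timm genes of mitochondrial protein import (0.451, adjusted p = 1.83e-05), 8 of 11 Coq genes of ubiquinone synthesis (0.522, adjusted p = 1.41e-04) and 10 of 14 Pex genes of peroxisome assembly (0.76, adjusted p = 3.61e-06). In the same cultures the general adipocyte list rose (1.78) and the macrophage list fell (-0.291). Toll-like receptor genes, many of them expressed by myeloid cells, fell, 7 of 11 with none higher (-0.393, adjusted p = 0.0243). Of 11 interferon-inducible Ifi genes 7 fell and 1 rose (-0.484, adjusted p = 0.0243). Sorting nexin genes fell in 8 of 29, against 2468 of all 13173 tested genes (-0.235, adjusted p = 0.0145, and -0.181 after centring on the median). All these means kept their sign after a second quantile normalization and after centring on the median.

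In the patterns that follow, the tests of the region within 100 genes of Lgr4 and of the control probe sets were fixed before their results were seen, and the tests between lists, their repeats and the test of the region within 3 genes of Lgr4 were chosen afterwards. The 3' minus 5' difference of the control probe sets, which RNA breakdown widens, shifted by -0.02 for Gapdh and 0.0195 for beta-actin between genotypes, against gaps of up to 0.018 and 0.107 within a genotype, all at signals near the top of the range.

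The thermogenic list rose, with 10 of 16 tested genes called higher, but did not pass with an estimated correlation (camera adjusted p = 0.233). Most adipocyte genes rose too, and more complete adipocyte conversion of the mutant cultures is a candidate explanation. That account needs the thermogenic genes to rise no more than the general adipocyte list, and their mean was lower by 0.608 (-0.608, 16 against 32 genes, two-sided permutation p over genes 0.143, adjusted p = 0.286 over 4 list comparisons). This difference did not pass, and the thermogenic list mean was nearer background in wild-type (6.92 against 9.615), where RMA compresses differences. The comparison therefore cannot separate this account from others. Against the white markers the thermogenic mean differed by 0.118 (16 against 14 genes, two-sided permutation p = 0.825, adjusted p = 0.825), so a rise beyond that of white genes cannot be told apart from none, because the members of both lists spread widely. A specific action of Lgr4 on thermogenic genes stays open, since genes are not independent replicates and the arrays measure mixed cultures.

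Means of the macrophage, matrix and mural lists fell in the mutant, and a larger share of adipocytes diluting all other cells could give such a fall. Called lower were 12 of 27, 21 of 36 and 10 of 19 tested genes, and 0, 6 and 3 were called higher. None of these lists passed with an estimated correlation (camera adjusted p = 0.397, 0.414 and 0.352). Dilution alone needs the markers of all other cells to fall alike where their signals lie well above background. The macrophage mean lay below the endothelial one (-0.472, 27 against 19 genes, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 4e-05). The gap ran from -0.525 to -0.419 without single arrays and was -0.549 against the 12 endothelial genes with a mean signal above 7. The wild-type list mean was 7.33 for endothelial and 12.2 for macrophage markers, and RMA compresses differences near background. Low endothelial signals can therefore fall little, but compression of a fall gives no rise. The endothelial mean was higher in the mutant by 0.181, and by 0.113 to 0.249 without single arrays. Over the 12 brighter endothelial genes it was higher by 0.258. For the endothelial markers these values argue against dilution alone. However, of the 19 endothelial genes 3 rose, 1 fell and 15 did not pass, and genes are not independent replicates. Macrophage and smooth muscle and mural lists differed by 0.0724 (two-sided permutation p = 0.636, adjusted p = 0.825), with a 95% bootstrap interval of -0.244 to 0.402. Dilution together with a change in the endothelial cells, and a lower expression in the macrophages themselves, stay open.

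Several genes next to Lgr4 were called lower, for which a strain haplotype carried along with the mutant allele or a local effect of the allele may account. Within 100 genes on either side, 43 of 120 tested genes (35.8%) were called against 30.3% elsewhere, an odds ratio of 1.29 (one-sided Fisher exact p = 0.113, adjusted p = 0.181 over 8 windows and kinds of call). Within 3 genes on either side, 4 of 6 (Bdnf, Lin7c, Ccdc34 and Fibin, not Kif18a or Bbox1) were lower against 19.3% elsewhere, an odds ratio of 8.39 (one-sided Fisher exact p = 0.0148, adjusted p = 0.0668), a window chosen after the values were seen. For Lin7c only the brightest probe set passed. Calls of either direction made up 6 of 9 genes within 10 genes (one-sided Fisher exact p = 0.0267, adjusted p = 0.0712) and 18 of 41 within 50 genes (43.9%, one-sided Fisher exact p = 0.0455, adjusted p = 0.091), windows not fixed in advance. All 8 odds ratios lay above 1 and none passed adjustment, so the haplotype, the local effect and chance stay open. The mutant allele's structure and the strain of the mice were not given in the sources used here.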
